A study of Rattus norvegicus with 12 samples.

How the data were processed

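The data are mRNA sequencing libraries from hypothalamic tissue containing the PVH of male Wistar rats, 12 libraries in 6 groups of 2. Per the labels, tissue was dissected on ice, RNA was extracted with Trizol and purified on columns with DNase digestion, libraries were made with the Illumina TruSeq RNA kit from total RNA, and they were sequenced on an Illumina HiSeq2000. The authors' processing notes list CASAVA 1.8.2, TopHat2 2.1.1, Cufflinks 2.2.1 and the rat genome build rn6. The role of each tool and the gene annotation are not given in the sources used here, so genes are identified by the symbols of the files and no gene positions are reported. Of 17310 identifiers, 701 carry no gene name and were counted but not named.

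Each deposited file is a Cuffdiff read group table of 1 library. The deposited raw fragments are expected counts per gene, which the authors left unscaled; 0.751% of the values, in 233 genes, were not whole and were rounded, by at most 0.5. The deposited FPKM values (fragments scaled to transcript length and library size), which the authors scaled within each run, and the deposited scaled fragments were made in 2 separate Cuffdiff runs. Per the file headers, sham, high Cort and ADX formed one run and supplemented ADX, 1 h acute and 3 h acute the other. Scaled values are therefore not comparable across the runs, and the tests used raw fragments; the scaled fragments were not used for tests. The comparisons of supplemented ADX with ADX and with sham, and of the acute groups with sham, cross the runs, so they would hold a difference between runs as well as one between groups. In 4 cells of 3 genes the files give the status FAIL; these counts were kept.

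Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 6 groups (minimum count 10, minimum total 15), which left 12856. Libraries were scaled by TMM, and 1 robust quasi-likelihood model with a coefficient per group was fitted to all 12 libraries, because 2 libraries per group leave few degrees of freedom for a fit of a pair of groups alone. It had 6 residual degrees of freedom, a median prior of 8.9 and a common biological coefficient of variation of 0.047. Each of 9 comparisons was tested with edgeR's quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjustment over the genes of the comparison, and a gene was called at an adjusted p under 0.05. A permutation of 4 libraries can give no p under 0.333, so the tests rest on the spread pooled over groups and genes. Replicate numbers were not used to pair libraries, since nothing in the labels ties them to an animal or day. Differences between comparisons were tested as contrasts of the same model. Overlaps between comparisons that share libraries were set against 40 simulated data sets with no effect and the same shared libraries, for genes with a mean CPM of at least 5 where correlations are given.

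The comparisons, the gene lists, the tests, the rule for named genes and the alternatives not marked as added were fixed before the data were examined. The 28 gene lists cover hormone-response pathways and markers of the cell types and neighbouring regions that the dissection could hold, and were written from general knowledge. Lists were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison. They were tested again with camera and an estimated correlation, and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. Of 252 list tests, 77 were called by camera, 37 up and 40 down, 14 by fry and none with an estimated correlation, where the lowest adjusted p was 0.057. For each comparison the rule named the 8 called genes with the highest and the 8 with the lowest log2 fold change among those with a mean log2 CPM of at least 1 and groups that do not overlap. It also named up to 4 genes of smallest p from each list. In every comparison it named Crh, Avp, Oxt, Trh, Nr3c1, Nr3c2, Fkbp5, Tsc22d3, Per1, Sgk1, Fos and Egr1. The text gives the part of these that it describes, and a few genes that the rule named are not reported here. Genes named only for the difference tests, the genes called in opposite directions in high Cort and ADX, and the vascular genes weighed in the closing section, with Abcg2 and Mfsd2a beside them, were chosen after their values were seen.

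The alternatives were RLE size factors, no filter on low counts, a stricter filter (CPM of at least 1 in at least 4 samples) and DESeq2 1.42.0. A further one was limma-trend (limma 3.58.1) on log2 FPKM with a pseudocount of 1 or 0.1 for genes with FPKM of at least 1 in at least 2 samples and within a run only. The rest were a fit of the 4 samples compared, a replicate block, and leaving out each library in turn with the other groups kept, which assumes that the lone library varies like the other groups. Added after the data were seen were the thalamus score (mean log2 CPM of 14 thalamus markers) as a covariate, a fit of the 6 samples of a run, and leaving out libraries for the difference tests. With every library thinned to the shallowest, the calls went from 1641 to 1567 and from 1026 to 816 in 1 h and 3 h acute against sham, from 6 to 12 and from 1 to 6 against supplemented ADX, and from 3 to 5 between the acute times. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

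The tests were checked on simulated data of 12856 genes in which 50 genes changed at each of several folds. For high Cort against sham edgeR recovered 60% of genes changed 1.3-fold, 76% at 1.5-fold, 86% at 2-fold and 98% at 4-fold, and 21 of 181 calls were false. In ADX against sham 17 of 188 calls were false and in 1 h acute against supplemented ADX 8 of 161, so that the false share exceeded the nominal share in the former pair of comparisons and was near it in the last. With no simulated change, each comparison gave between 0.6 and 1.4 calls on average over 40 data sets. In all these simulations, as in those for overlaps, genes varied independently of each other. They held no spread in tissue composition shared by many genes, so real libraries can give more calls and stronger correlations without a treatment effect. The replicates of each group were checked against counting noise: chi-square per degree of freedom was 3.04 to 8.08, and no files of a group were identical.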

Results

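RNA was sequenced from hypothalamic tissue containing the paraventricular nucleus (PVH), which holds the neurons that drive the pituitary and adrenal response to stress. The tissue came from male Wistar rats aged 12 weeks. The 12 libraries formed 6 groups of 2. They were sham-operated rats (sham), rats given high corticosterone for 12 days (high Cort) and rats 7 days after removal of the adrenal glands (ADX). The others were adrenalectomised rats given corticosterone (supplemented ADX) and rats sampled 1 h or 3 h after acute corticosterone (1 h acute and 3 h acute). Corticosterone is the main glucocorticoid of the rat. The labels did not say whether the acutely treated rats were intact or adrenalectomised, no group was named as a vehicle control, and nothing said whether a replicate was 1 animal or a pool. Both acute groups were therefore compared with sham and with supplemented ADX.

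The total fragment count was 25724232 and 27797278 in the sham libraries, 25294220 and 31000682 in high Cort, and 33137737 and 31262274 in ADX. It was 36249006 and 31810257 in supplemented ADX, 32201860 and 17674159 in 1 h acute, and 20684695 and 22003888 in 3 h acute. Of 17310 genes in the files, 12856 were tested. Levels are given below in counts scaled to library size (CPM) as mean ± SD of 2 libraries, changes as log2 fold change ± SE, and adjusted p values come from edgeR's quasi-likelihood test unless another test is named. In every comparison, each called gene had both libraries of one group above both of the other, an order that chance gives to 33.3% of genes. The p values measure only the spread between these libraries, which can be technical.

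The mean level of 14 markers of the thalamus, the region next to the dissected tissue, differed between groups. On the log2 CPM scale this thalamus score was 7.16 in sham, 7.24 in high Cort, 6.73 in ADX, 6.79 in supplemented ADX, 6.14 in 1 h acute and 6.47 in 3 h acute. Within groups it was 6.97 and 7.35 in the sham libraries and 6.50 and 5.78 in the 1 h acute libraries. The 18S ribosomal RNA gene Rn18s stood at 3568.2 CPM in high Cort replicate 1 and between 563.2 and 1717.8 CPM in the others.

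**Figure D1:**
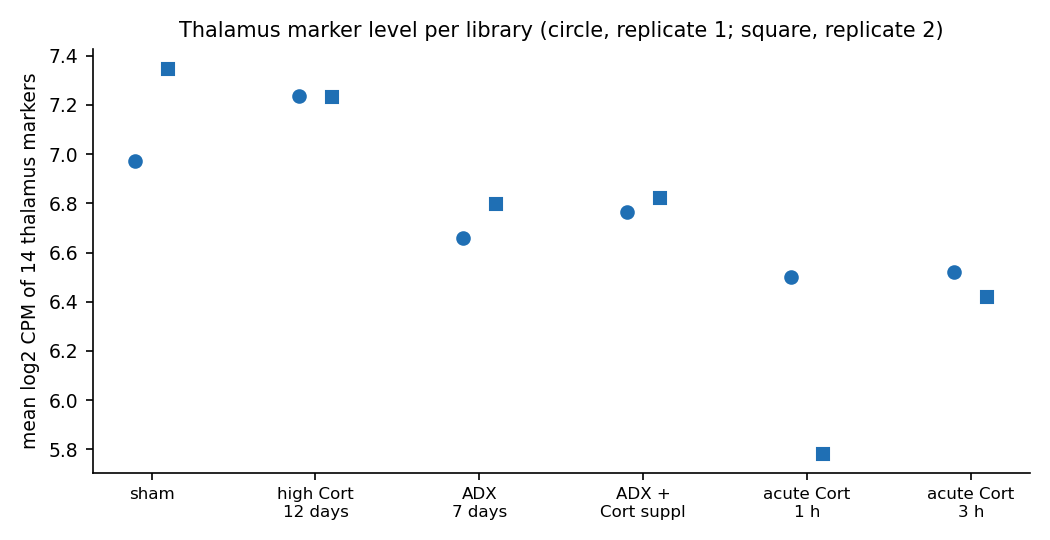
Thalamus score (mean log2 CPM of 14 thalamus markers) on the vertical axis, for each library by group on the horizontal axis, with 1 point per library. The group means, which are not drawn, ranged from 7.24 in high Cort to 6.14 in 1 h acute.

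The comparison of high Cort with sham asked what sustained excess of corticosterone changed in this tissue. Crh, which encodes the corticotropin-releasing hormone of the PVH, fell from 11.99 ± 2.09 to 3.25 ± 1.28 CPM, a 3.61-fold lower level (log2 fold change -1.85 ± 0.27, adjusted p = 0.0170, n = 2 per group). Some genes known to be induced through the glucocorticoid receptor rose. Hif3a, a subunit of the hypoxia-inducible factor family, rose from 0.975 ± 0.38 to 6.84 ± 1.15 CPM (2.79 ± 0.39, adjusted p = 0.00896). Gpd1, which links glycolysis to lipid synthesis, rose from 30.35 ± 5.35 to 113.7 ± 14.9 CPM (1.91 ± 0.16, adjusted p = 0.00146). Sgk1, the serum and glucocorticoid-regulated kinase, rose from 31.18 ± 1.61 to 79.67 ± 17.8 CPM (1.35 ± 0.13, adjusted p = 0.00111). The vascular endothelial growth factor receptor gene Kdr fell from 50.84 ± 0.50 to 28.07 ± 2.79 CPM (-0.85 ± 0.08, adjusted p = 6.4e-05).

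Among 39 tested genes of the glucocorticoid-induced list, 15 rose and none fell over all genes tested, and 24 rose and 1 fell adjusted over the list alone. Besides the genes above they included Fkbp5, a co-chaperone of the glucocorticoid receptor (0.56 ± 0.09, adjusted p = 0.00532), and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper (0.42 ± 0.08, adjusted p = 0.0340). Others were Klf9 (0.44 ± 0.04, adjusted p = 9.2e-05) and Zbtb16 (1.09 ± 0.17, adjusted p = 0.0208). Tsc22d3 lost the call in 8 of 14 alternatives, with log2 fold changes from 0.25 to 0.56. The list as a whole ranked high by camera (adjusted p = 3.80e-26, median log2 fold change 0.41; adjusted p = 0.14 with an estimated correlation), and fry gave 0.00824. Of 18 clock genes, Per1 (0.90 ± 0.08), Per2 (0.47 ± 0.05) and Per3 (0.29 ± 0.05) rose over all genes and 5 were called adjusted over the list alone. Camera gave the list an adjusted p of 0.00245 (0.14 with an estimated correlation), and 0.0946 without sham replicate 1.

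Of 17 endothelial and mural cell markers, 4 fell over all genes: Kdr, Itm2a (-0.41 ± 0.07), Slco1c1 (-0.35 ± 0.05) and the pericyte marker Pdgfrb (-0.30 ± 0.06). Adjusted over the list alone, 9 were lower and 1 higher (camera adjusted p = 2.48e-07, fry 0.0136; adjusted p = 0.14 with an estimated correlation). Other genes of endothelial cells among the lowest were Cd93 (from 34.78 ± 3.03 to 15.73 ± 1.47 CPM, -1.14 ± 0.12, adjusted p = 0.000617), Clec14a (-0.86 ± 0.11) and Pcdh12 (-1.67 ± 0.29), while Abcg2 (0.91 ± 0.07) and Mfsd2a (0.61 ± 0.09), genes of brain endothelium too, rose. The apelin receptor gene Aplnr (-0.87 ± 0.16) was among the lowest too. The matrix metalloproteinase gene Mmp14 (-1.30 ± 0.14), the lipid-binding protein gene Fabp7 of radial glia and astrocytes (-1.06 ± 0.10), the intermediate filament gene Nes (-0.79 ± 0.09) and Enpp6, a marker of newly forming oligodendrocytes (-0.90 ± 0.15), fell as well. Of 15 astrocyte markers Gfap (-0.41 ± 0.07) and Aqp4 (-0.26 ± 0.05) fell over all genes and 9 had a positive log2 fold change (camera adjusted p = 0.744); Aqp4 lost the call in 7 of 14 alternatives. Among the genes with the highest fold changes were Ctgf (1.40 ± 0.22), the macrophage scavenger receptor gene Cd163 (1.33 ± 0.17), the thiamine transporter gene Slc19a3 (1.16 ± 0.20) and Gpatch4 (0.95 ± 0.11). The thalamus score differed by less between these groups than between the sham libraries, while Rn18s was highest in high Cort replicate 1. The summed level of the hemoglobin genes Hbb, Hba1 and Hba2 was 25.17 and 21.86 CPM in high Cort against 35.42 and 40.47 CPM in sham.

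Among 31 neuropeptide genes, Crh passed over all genes, and Crh, Avp and Pcsk1 were lower adjusted over the list alone, with no call for the list (camera adjusted p = 0.119). Avp, which encodes vasopressin, stood at 66.56 ± 12 against 99.18 ± 5.57 CPM (-0.58 ± 0.12, adjusted p = 0.0982), and Oxt, which encodes oxytocin, at 194.1 ± 21.1 against 301.9 ± 115 CPM (-0.64 ± 0.26, adjusted p = 0.579).

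In all, edgeR called 112 genes, 66 higher and 46 lower, of which 16 changed at least 2-fold, and 1075 genes had an unadjusted p under 0.05. The count was 23 without high Cort replicate 1, 40 without sham replicate 2, 46 in a fit of the 4 samples alone, and 69 and 67 by limma-trend on FPKM. It was 175 with the thalamus score as a covariate, an alternative added after the data were seen. Of 37 called genes named in the text for this comparison, 14 kept the call without each of the 4 libraries in turn, among them Per1, Sgk1, Gpd1, Klf9, Kdr, Cd93 and Mmp14. Crh had an adjusted p of 0.0972 without sham replicate 2, 0.0708 without high Cort replicate 1 and 0.0765 in the fit of 4 samples. Hif3a had 0.0617 without sham replicate 1 and 0.0941 without high Cort replicate 1. Fkbp5 had 0.0720 without sham replicate 2 and 0.0708 without high Cort replicate 1, and Sgk1 had 0.185 in the fit of 4 samples.

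**Figure D2:**
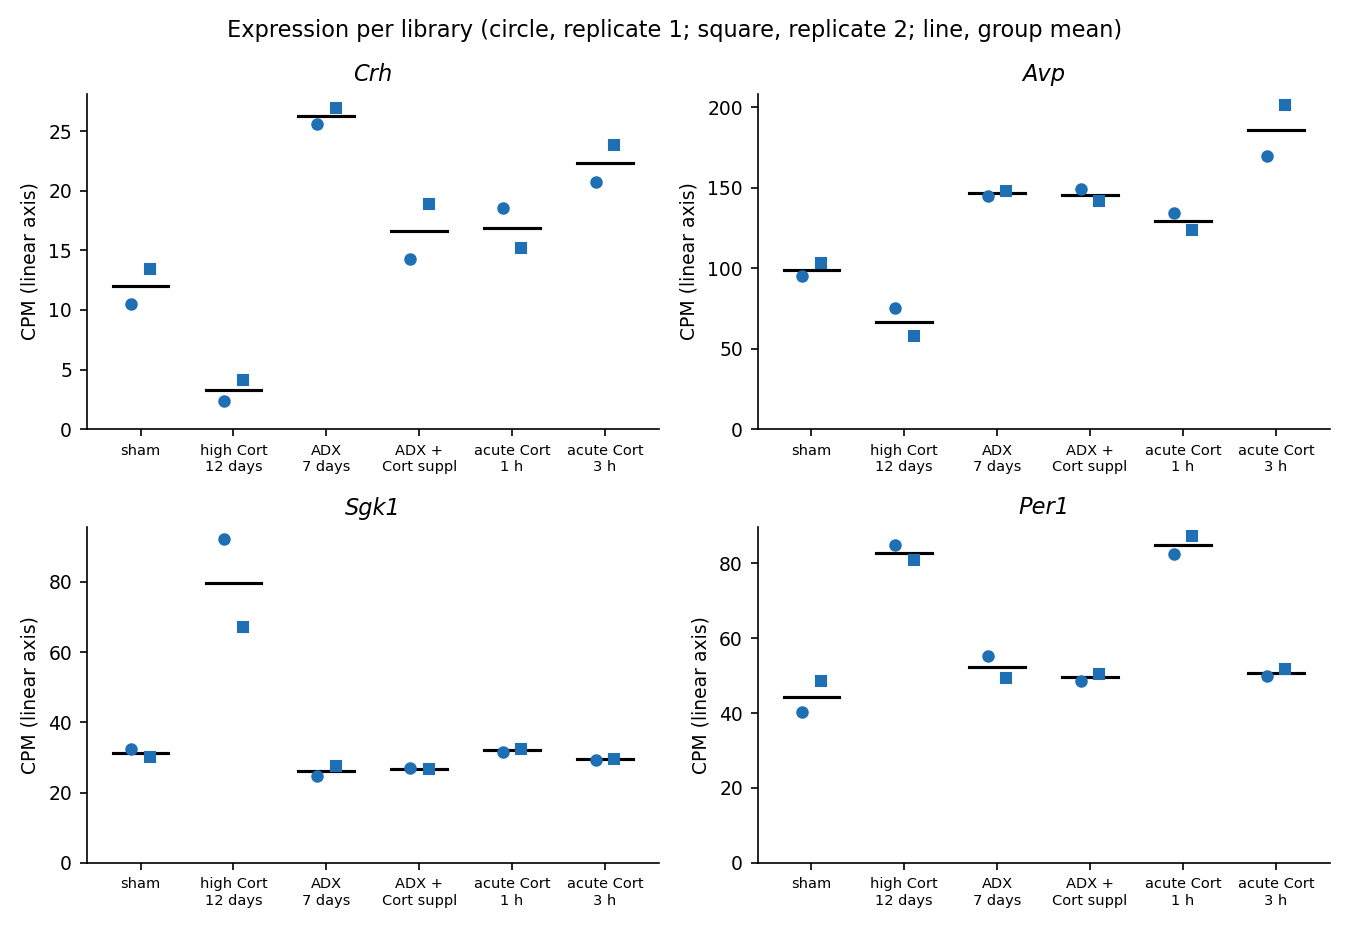
Levels of Crh, Avp, Sgk1 and Per1 in CPM on a linear vertical axis for each library by group on the horizontal axis, with points for libraries and a bar for the group mean. Mean Crh was 11.99 CPM in sham, 3.25 CPM in high Cort and 26.24 CPM in ADX, and mean Sgk1 was 79.67 CPM in high Cort against 31.18 CPM in sham.

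The comparison of ADX with sham asked what the loss of adrenal hormones changed. Htra1, which encodes a secreted serine protease, fell from 66.36 ± 1.06 to 36.41 ± 3.7 CPM (-0.86 ± 0.08, adjusted p = 0.00103, n = 2 per group). The iron oxidase gene Heph fell from 33.61 ± 1.43 to 16.02 ± 0.284 CPM (-1.07 ± 0.13, adjusted p = 0.0106). The DNA topoisomerase gene Top2a of dividing cells rose from 1.00 ± 0.0311 to 2.95 ± 0.372 CPM (1.55 ± 0.26, adjusted p = 0.0244). The clock genes Per3 (0.46 ± 0.05, adjusted p = 0.00217) and Per2 (0.42 ± 0.05, adjusted p = 0.00411) rose. Crh stood at 26.24 ± 0.96 against 11.99 ± 2.09 CPM, a 2.18-fold higher mean that did not pass the test (1.13 ± 0.20, adjusted p = 0.0695). Avp stood at 146.6 ± 2.22 against 99.18 ± 5.57 CPM (0.56 ± 0.12, adjusted p = 0.121).

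Other genes that fell were Aifm3 (-0.54 ± 0.07), Cyp4f4 (-0.88 ± 0.14), Gimap8 (-0.79 ± 0.14), Fabp7 (-0.52 ± 0.09), the proline dehydrogenase gene Prodh (-0.41 ± 0.07), the efflux transporter gene Abcg2 (-0.41 ± 0.07) and Slco1c1 (-0.30 ± 0.05). Others that rose were Aplnr (0.76 ± 0.14), the potassium channel subunit gene Kcng1 (0.69 ± 0.12), Palmd (0.48 ± 0.09), the enkephalin precursor gene Penk (0.48 ± 0.08), Igfbp5 (0.46 ± 0.07) and the receptor gene Gpr101 (0.40 ± 0.06).

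Of 18 cell cycle genes, Top2a rose over all genes, and Top2a, Cenpf (0.70 ± 0.21) and Mki67 (0.55 ± 0.13) were higher adjusted over the list alone (camera adjusted p = 1.23e-05, fry 0.00966; adjusted p = 0.057 with an estimated correlation). No neuron marker of 15 passed over all genes and 6 were lower adjusted over the list alone (camera adjusted p = 1.23e-05; adjusted p = 0.534 with an estimated correlation). All 14 thalamus markers had a negative log2 fold change and none passed (camera adjusted p = 2.34e-05; adjusted p = 0.685 with an estimated correlation). Of 31 neuropeptide genes, Penk rose over all genes, and 5 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00872; adjusted p = 0.534 with an estimated correlation). Camera gave this list 0.0559 without sham replicate 2 and 0.131 with the thalamus score as a covariate. Of 20 markers of the suprachiasmatic nucleus and anterior hypothalamus, 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00317; adjusted p = 0.13 with an estimated correlation; 0.0748 with the thalamus score). Adjusted over the list alone, 1 of the 39 glucocorticoid-induced genes was higher and 2 were lower, with none called over all genes (camera down, adjusted p = 0.0234; adjusted p = 0.741 with an estimated correlation; 0.0989 without ADX replicate 2).

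In this comparison edgeR called 30 genes, 17 higher and 13 lower, with 1647 at an unadjusted p under 0.05. The count was 4 without ADX replicate 1, 7 without ADX replicate 2, 10 without sham replicate 2 and 148 without sham replicate 1. DESeq2 called 123, a fit of the 6 samples of the processing run 99, limma-trend on FPKM 8, an unfiltered fit 48, and the fit with the thalamus score 14. Of 20 called genes named here, Htra1 and Per3 kept the call without each library in turn and the rest lost it in at least 1 such fit. Top2a had an adjusted p of 0.154 without sham replicate 2, 0.117 without ADX replicate 1 and 0.224 without ADX replicate 2. With the thalamus score 8 kept the call, among them Htra1, Per2, Per3 and Top2a. Among those that lost it, over all alternatives Heph lay between -1.12 and -0.90, Prodh between -0.46 and -0.36 and Abcg2 between -0.46 and -0.34. Cyp4f4 (-0.96 to -0.57) and Penk (0.35 to 0.63) varied more. DESeq2 gave no adjusted p for Abcg2, Cyp4f4, Top2a and some other genes named here, so its 123 calls did not include them.

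High Cort and ADX lie at opposite ends of corticosterone exposure, and the overlap of their changes from the shared sham libraries was tested. Of the called genes, 5 rose in high Cort and fell in ADX (Abcg2, Aifm3, Dusp3, Htra1, Prodh), where independent calls would give 0.0667. Another 3 fell in high Cort and rose in ADX (Aplnr, Igfbp5, Slc7a11), against 0.0608. Per2 and Per3 rose in both groups, against 0.0873, and Fabp7 and Slco1c1 fell in both, against 0.0465, where the shared control favours the same direction. Across 10180 genes, which are not independent replicates, the 2 sets of log2 fold changes correlated at 0.279, below the 0.513 that the shared control gave in 40 simulations, and their covariance was 0.00703 against 0.00518. The direct contrast of the groups called 742 genes, 450 higher and 292 lower in high Cort than in ADX. It gave log2 differences of -2.98 ± 0.24 for Crh (adjusted p = 0.00031), -1.14 ± 0.12 for Avp (adjusted p = 0.0015), 1.36 ± 0.08 for Htra1 (adjusted p = 1.7e-06) and -1.63 ± 0.15 for Aplnr (adjusted p = 3.0e-05). It called neither Per2 (0.05, adjusted p = 0.66) nor Per3 (-0.17, adjusted p = 0.067). The count was 282 with the thalamus score, 157 without high Cort replicate 1, 386 without high Cort replicate 2, 219 without ADX replicate 1 and 218 without ADX replicate 2.

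The comparison of supplemented ADX with ADX asked how adrenalectomised rats given corticosterone differed from those 7 days after surgery without it. The labels gave no duration for supplemented ADX, so the time since surgery may differ between the groups. The comparison crossed the 2 processing runs, as did every comparison below that sets supplemented ADX or an acute group against sham or ADX and would hold a difference between runs as well. Htra1 rose from 36.41 ± 3.7 to 56.48 ± 4.43 CPM (0.63 ± 0.08, adjusted p = 0.0149, n = 2 per group) and Aifm3 from 41.8 ± 0.978 to 58.6 ± 4.21 CPM (0.49 ± 0.07, adjusted p = 0.0149). Slc7a11, which encodes the cystine and glutamate exchanger, fell from 191.8 ± 10 to 140.6 ± 1.78 CPM (-0.45 ± 0.06, adjusted p = 0.0149). Igfbp5, an insulin-like growth factor binding protein gene, fell from 110.5 ± 7.94 to 79.64 ± 2.29 CPM (-0.47 ± 0.07, adjusted p = 0.0330). These 4 genes were all that edgeR called, and all had moved the other way in ADX against sham. Over 10180 genes the 2 sets of log2 fold changes correlated at -0.409, no more strongly than the -0.48 in simulation, with a covariance of -0.00639 against -0.00472. Of the 30 genes with the smallest p in ADX against sham, 27 lay on the other side of 0, against 27.8 in simulation. Crh stood at 16.59 ± 3.27 against 26.24 ± 0.96 CPM (-0.67 ± 0.18, adjusted p = 1).

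The 8 genes called in opposite directions in high Cort and ADX were chosen after their values were seen. Their side of 0 in supplemented ADX against ADX is not a test, since both comparisons share the ADX libraries. Among those not called there, Abcg2 had 0.40 (adjusted p = 0.10), Prodh 0.47 (adjusted p = 0.065), Dusp3 0.14 (adjusted p = 1) and Aplnr -0.30 (adjusted p = 1). In high Cort against sham, Abcg2 had 0.91 ± 0.07 and Htra1 0.50 ± 0.08.

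**Figure D3:**
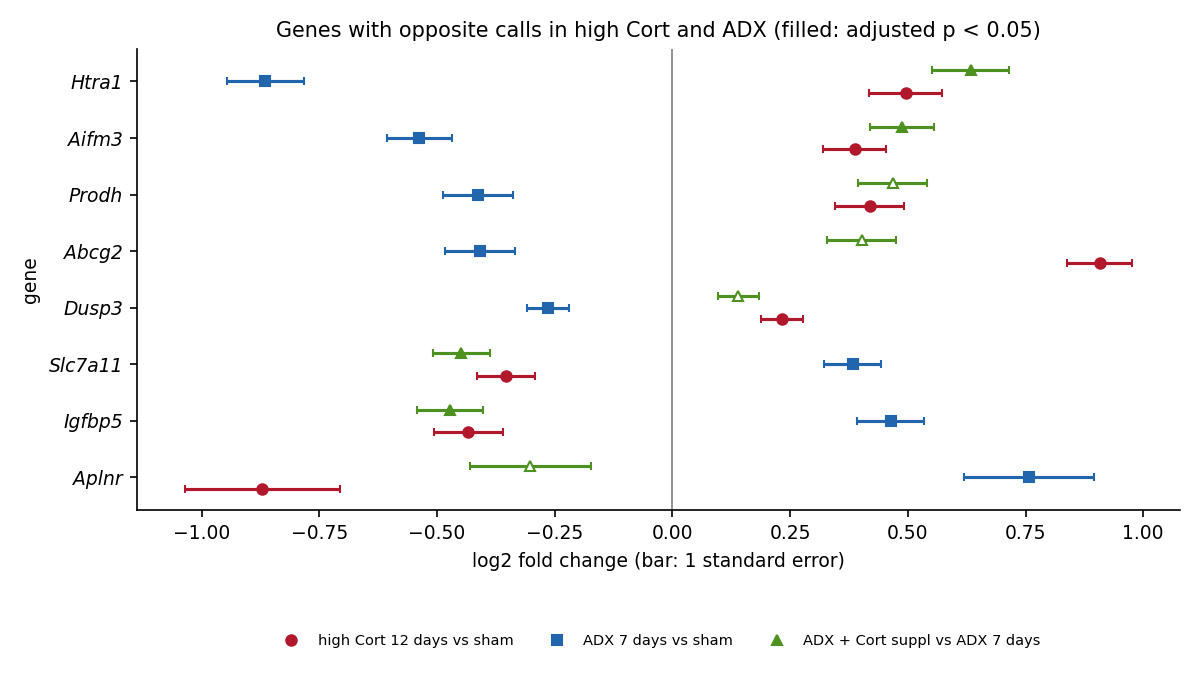
Log2 fold change with 1 SE (horizontal axis) of the 8 genes called in opposite directions in high Cort and ADX, listed on the vertical axis, for high Cort against sham, ADX against sham and supplemented ADX against ADX. Filled symbols mark an adjusted p under 0.05; Htra1 had 0.50, -0.86 and 0.63.

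Of the 39 glucocorticoid-induced genes, 32 had a positive log2 fold change in supplemented ADX against ADX and none passed over all genes. The connexin gene Gjb6 (0.36 ± 0.08), the glutamine synthetase gene Glul (0.26 ± 0.07), Gpd1 (0.73 ± 0.16) and Mfsd2a (0.41 ± 0.09) were higher adjusted over the list alone (camera adjusted p = 1.31e-06; adjusted p = 0.644 with an estimated correlation). In the ribosomal protein list, 77 of 87 genes were positive with a median of 0.10 and none called (camera adjusted p = 7.46e-13; adjusted p = 0.644 with an estimated correlation); 6 of its members encode ribosomal S6 kinases. Genes of the mitochondrial respiratory chain were positive in 60 of 72 (camera adjusted p = 1.05e-07; adjusted p = 0.675 with an estimated correlation; 0.0632 without supplemented ADX replicate 2). Cell cycle genes were negative in 15 of 18 (camera adjusted p = 0.000195; adjusted p = 0.131 with an estimated correlation).

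At an unadjusted p under 0.05, 521 genes differed. Simulated data with no effect gave 1.4 calls on average and at most 8 in this comparison. Without ADX replicate 2 or without supplemented ADX replicate 1 edgeR called no gene, with 407 and 470 at an unadjusted p under 0.05. DESeq2 called 14, a fit of the 4 samples 33 and the fit with the thalamus score 7, which kept all 4 genes.

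The comparison of supplemented ADX with sham asked what difference remained. Fabp7 fell from 27.12 ± 2.84 to 16.25 ± 0.694 CPM (-0.74 ± 0.09, adjusted p = 0.0105, n = 2 per group). Per2 rose from 54.57 ± 0.271 to 70.13 ± 1.83 CPM (0.36 ± 0.05, adjusted p = 0.0340). These were the 2 genes called. Avp stood at 145.3 ± 5.05 against 99.18 ± 5.57 CPM (0.55 ± 0.12, adjusted p = 0.220) and Crh at 16.59 ± 3.27 against 11.99 ± 2.09 CPM (0.46 ± 0.20, adjusted p = 0.501). Of 31 neuropeptide genes, 8 were higher and 2 lower adjusted over the list alone and none over all genes (camera adjusted p = 0.000464; adjusted p = 0.509 with an estimated correlation). All 14 thalamus markers were negative (camera adjusted p = 0.000178; adjusted p = 0.667 with an estimated correlation; 0.101 without sham replicate 2). Of the others, 2 of 15 neuron markers were lower adjusted over the list alone (camera adjusted p = 6.15e-05; adjusted p = 0.565 with an estimated correlation). Ribosomal protein genes were positive in 72 of 87 (camera adjusted p = 5.19e-06; adjusted p = 0.667 with an estimated correlation).

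At an unadjusted p under 0.05, 1287 genes differed, and simulated data with no effect gave 1.15 calls on average and at most 5. Without supplemented ADX replicate 1 or replicate 2 edgeR called no gene, with 736 and 967 at an unadjusted p under 0.05; it called 64 without sham replicate 1 and 3, with no gene in common, without sham replicate 2. DESeq2 called 42, a fit of the 4 samples 23, an unfiltered fit 11, the fit with the thalamus score 5, and a fit with RLE size factors 3, of which 2 were higher.

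The comparison of 1 h acute with sham asked for the early response to corticosterone. Some immediate early genes, which rise within minutes of stimulation, were higher, although their list was not called. Nr4a3 rose from 7.41 ± 2.15 to 24.57 ± 1.96 CPM (1.71 ± 0.21, adjusted p = 0.00345, n = 2 per group). Fos rose from 8.68 ± 0.988 to 23.22 ± 2.37 CPM (1.41 ± 0.34, adjusted p = 0.0421), and Egr1 from 18.08 ± 6.06 to 42.51 ± 4.42 CPM (1.23 ± 0.23, adjusted p = 0.0166). Per1 rose from 44.42 ± 6.01 to 84.93 ± 3.47 CPM (0.93 ± 0.08, adjusted p = 0.00013) and Per2 from 54.57 ± 0.271 to 93.31 ± 3.23 CPM (0.77 ± 0.05, adjusted p = 4.0e-06). The protein kinase gene Prkcd, on the list of thalamus markers, fell from 331.1 ± 114 to 80.77 ± 56.3 CPM (-1.99 ± 0.47, adjusted p = 0.0444).

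Of 35 immediate early genes, 8 rose and 3 fell over all genes and 10 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0538). Fosb (1.47 ± 0.33), Fosl2 (0.96 ± 0.17), Nr4a1 (0.95 ± 0.16) and Junb (0.62 ± 0.13) were among those that rose. The kinase gene Sik1 (0.87 ± 0.12) and Per3 (0.47 ± 0.05) rose as well. Nr3c1, which encodes the glucocorticoid receptor, fell from 228.5 ± 10.9 to 198.6 ± 12.6 CPM (-0.20 ± 0.06, adjusted p = 0.0439). The cholesterol synthesis gene Srebf2 (0.18 ± 0.05) rose. Nr3c1 and Srebf2 with the thalamus score changed sign and were not called.

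Of 14 thalamus markers, 10 fell over all genes and all 14 were lower adjusted over the list alone (camera adjusted p = 4.26e-09; adjusted p = 0.546 with an estimated correlation). They included Ramp3 (-1.52 ± 0.27), Synpo2 (-1.26 ± 0.28), Lef1 (-1.21 ± 0.20) and the glutamate transporter gene Slc17a6 (-0.66 ± 0.11). Of 15 neuron markers, 8 fell over all genes and 11 adjusted over the list alone, Snap25 (-0.29 ± 0.05) and Nefm (-0.38 ± 0.06) among them (camera adjusted p = 3.48e-05; adjusted p = 0.546 with an estimated correlation). Among 31 neuropeptide genes, 6 rose and 3 fell over all genes and 9 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0101; adjusted p = 0.546 with an estimated correlation). Gal (0.85 ± 0.12) and Penk (0.63 ± 0.08) were higher and Vip lower, at 0.756 ± 0.677 against 4.95 ± 2.11 CPM (-2.50 ± 0.51). Of 20 suprachiasmatic and anterior hypothalamic markers, 6 rose and 2 fell over all genes and 11 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00148; adjusted p = 0.19 with an estimated correlation). Fezf1 (1.38 ± 0.25), Isl1 (0.56 ± 0.13) and Pou3f2 (0.36 ± 0.05) were higher. The transcription factor genes Hmx3 (1.23 ± 0.25), Onecut1 (1.03 ± 0.30) and Vax1 (0.97 ± 0.25) were among the highest, and Gabrd (-1.88 ± 0.36), Shox2 (-1.43 ± 0.30), Epha1 (-1.29 ± 0.21) and Chst9 (-1.25 ± 0.24) among the lowest. In the mitochondrial list 5 of 72 fell over all genes and 1 adjusted over the list alone (camera adjusted p = 0.000644; adjusted p = 0.693 with an estimated correlation). The thalamus score was 6.14 in 1 h acute and 7.16 in sham.

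The test called 1641 genes, 715 higher and 926 lower, with 3521 at an unadjusted p under 0.05 and 56 changed at least 2-fold. The fit with the thalamus score gave 2, with 534 at an unadjusted p under 0.05. The median log2 fold change of the 1641 genes toward their call went from 0.302 to 0.101, and 1417 kept their direction. The median of the SEs of the single genes went from 0.070 to 0.110. Of 33 called genes named here Per2 alone kept the call. The fold changes of Per1 (0.931 to 0.938), Nr4a3 (1.71 to 1.63) and Fezf1 (1.385 to 1.376) stayed about as large. That of Prkcd went from -1.99 to -0.05, but Prkcd is itself part of the score, so its shrinking is no test. Over all alternatives the log2 fold change went as low as 0.37 for Fosb, 0.66 for Egr1, 0.42 for Gal and 0.33 for Penk. The count was 144 without sham replicate 2, 315 without 1 h acute replicate 2 and 23 in a fit of the 4 samples. In all, 10 of the 33 kept the call without each library in turn: Per1, Per2, Per3, Nr4a3, Fosl2, Sik1, Gal, Penk, Pou3f2 and Snap25.

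The comparison of 3 h acute with sham asked for the later response. Avp rose from 99.18 ± 5.57 to 185.7 ± 22.2 CPM (0.90 ± 0.12, adjusted p = 0.00741, n = 2 per group). Crh rose from 11.99 ± 2.09 to 22.29 ± 2.15 CPM (0.89 ± 0.21, adjusted p = 0.0357) and Trh, which encodes thyrotropin-releasing hormone, from 66.92 ± 6.22 to 110 ± 20.3 CPM (0.72 ± 0.13, adjusted p = 0.0193). Avp also stood above sham in supplemented ADX (148.9 and 141.8 CPM) and in ADX (145.0 and 148.2 CPM). So did Crh, at 14.3 and 18.9 CPM in supplemented ADX and 25.6 and 26.9 CPM in ADX. Against supplemented ADX, Avp, Crh and Trh were not called at 3 h. The cholesterol synthesis genes Idi1, from 49.54 ± 3.66 to 38.38 ± 1.27 CPM (-0.37 ± 0.07, adjusted p = 0.00752), and Insig1, from 187.9 ± 1.33 to 152.2 ± 9.59 CPM (-0.30 ± 0.05, adjusted p = 0.00386), fell.

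Of 31 neuropeptide genes, 12 rose and 3 fell over all genes and 13 rose and 3 fell adjusted over the list alone (camera adjusted p = 6.87e-06; adjusted p = 0.207 with an estimated correlation). Gal (0.80 ± 0.12) and Penk (0.77 ± 0.08) rose, and Vip (-2.16 ± 0.51) and the prohormone convertase gene Pcsk2 (-0.40 ± 0.06) fell. Of 25 cholesterol synthesis genes, 6 fell over all genes and 7 adjusted over the list alone, Stard4 (-0.31 ± 0.05) among them. Camera gave the list an adjusted p of 0.0338 (0.673 with an estimated correlation, 0.325 without sham replicate 1 and 0.247 without 3 h acute replicate 1). The hemoglobin genes Hba2 (1.14 ± 0.17) and Hbb (0.66 ± 0.13) rose, as 2 of 7 erythroid genes over all genes and adjusted over the list alone. Camera gave 0.0197 for the list (0.673 with an estimated correlation, 0.121 without sham replicate 1 and 0.133 without 3 h acute replicate 2). Of 14 thalamus markers, Lef1 (-0.99 ± 0.20) and Slc17a6 (-0.57 ± 0.11) fell over all genes and 9 adjusted over the list alone (camera adjusted p = 6.50e-06; adjusted p = 0.673 with an estimated correlation). Of 15 neuron markers, 4 fell over all genes and 9 adjusted over the list alone (camera adjusted p = 0.0105; adjusted p = 0.673 with an estimated correlation). The suprachiasmatic and anterior hypothalamic list had 6 of 20 higher and 2 lower over all genes, and 9 and 3 adjusted over the list alone (camera adjusted p = 0.00167; adjusted p = 0.197 with an estimated correlation).

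Among the highest were Fezf1 (1.29 ± 0.26), Hmx3 (1.22 ± 0.26), Vax1 (1.13 ± 0.25), Dlx2 (0.93 ± 0.13) and Dlx5 (0.92 ± 0.21). Sspo, a gene of the subcommissural organ, had 0.95 ± 0.26. The lowest included Gabrd (-1.58 ± 0.36), Ifit1 (-1.49 ± 0.33), Chst9 (-1.28 ± 0.25), Il12rb2 (-1.21 ± 0.24), Casq2 (-1.13 ± 0.26), Sptssb (-1.04 ± 0.25) and Pygl (-1.03 ± 0.23). Per2 (0.56 ± 0.05), Per3 (0.28 ± 0.05) and Zbtb16 (0.71 ± 0.18) rose and Nr3c1 (-0.26 ± 0.06) fell. The thalamus score was 6.47 in 3 h acute and 7.16 in sham.

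The test called 1026 genes, 438 higher and 588 lower, with 3217 at an unadjusted p under 0.05 and 20 changed at least 2-fold. The thalamus score reduced the count to 7, with 901 at an unadjusted p under 0.05. The median log2 fold change toward the call went from 0.292 to 0.165, and the median of the SEs of the single genes from 0.066 to 0.085. Penk and Per2 kept the call among 31 called genes named here. Per2 was called above sham in high Cort (0.47), ADX (0.42), supplemented ADX (0.36) and 1 h acute (0.77) as well. Neither Penk nor Per2 was called in 3 h acute against supplemented ADX. Over all alternatives the log2 fold changes of Dlx2 (0.87 to 1.00) and Avp (0.78 to 1.03) stayed near those of the main fit. Those of Vip (-2.52 to -0.14) and Gabrd (-1.88 to -0.32) did not. The count was 81 without sham replicate 2, 96 without 3 h acute replicate 2 and 478 without 3 h acute replicate 1. Gal, Penk, Dlx2, Insig1 and Per2 kept the call without each library in turn. Crh had an adjusted p between 0.0835 and 0.207 in all 4 such fits and Avp 0.0530 without sham replicate 2.

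The comparison of 1 h acute with supplemented ADX asked the early question again, within 1 processing run. Per1 rose from 49.57 ± 1.27 to 84.93 ± 3.47 CPM (0.77 ± 0.08, adjusted p = 0.00174, n = 2 per group) and Per2 from 70.13 ± 1.83 to 93.31 ± 3.23 CPM (0.41 ± 0.05, adjusted p = 0.00588). The RNA-binding protein gene Hnrnpc fell from 70.92 ± 6.29 to 50.22 ± 3.11 CPM (-0.49 ± 0.07, adjusted p = 0.0115). Fam46a (0.59 ± 0.09), the imprinted gene Zim1 (0.50 ± 0.08) and the kinase gene Map3k13 (0.42 ± 0.07) rose with an adjusted p of 0.0340 each.

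No immediate early gene of 35 passed over all genes, although Nr4a3, Egr1 and Fos passed in a fit of the 4 samples (adjusted p = 0.00111, 0.0123 and 0.0159), and these with Junb and Nr4a1 in a fit of the run's 6 samples. Adjusted over the list alone, Egr1, Egr3, Fosb, Fosl2, Junb, Nr4a1 and Nr4a3 were higher and Klf6 was lower. Camera gave the list an adjusted p of 0.00339 (0.564 with an estimated correlation, 0.0727 without 1 h acute replicate 1 and 0.0508 with the thalamus score). Nr4a3 stood at 24.57 ± 1.96 against 9.55 ± 0.616 CPM (1.36 ± 0.20, adjusted p = 0.0650). Egr1 stood at 42.51 ± 4.42 against 21.51 ± 1.92 CPM (0.97 ± 0.22, adjusted p = 0.165) and Fos at 23.22 ± 2.37 against 11.49 ± 1.27 CPM (1.01 ± 0.32, adjusted p = 0.251). Sgk1 (0.26 ± 0.13, adjusted p = 0.397) and Fkbp5 (-0.13 ± 0.09, adjusted p = 0.535) were not called. All 14 thalamus markers were negative, with 4 lower adjusted over the list alone (camera adjusted p = 8.47e-09; adjusted p = 0.564 with an estimated correlation). So were 3 of 15 neuron markers (camera adjusted p = 0.00888; adjusted p = 0.678 with an estimated correlation; turned with the thalamus score, 0.929). Ribosomal protein genes were positive in 11 of 87 (camera adjusted p = 1.85e-10; adjusted p = 0.564 with an estimated correlation) and mitochondrial genes in 9 of 72 (camera adjusted p = 2.04e-08; adjusted p = 0.564 with an estimated correlation).

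Here edgeR called 6 genes, 5 higher and 1 lower, with 1891 at an unadjusted p under 0.05; simulated data with no effect gave 1.05 on average and at most 5. The count was 624 without 1 h acute replicate 1, 1 without 1 h acute replicate 2, 2 without supplemented ADX replicate 1 and 1 without supplemented ADX replicate 2, and Per1 kept the call in all 4 fits. In the fit with the thalamus score edgeR called no gene, with 629 at an unadjusted p under 0.05. The median log2 fold change of the 6 genes toward their call went from 0.496 to 0.376 and the median of their SEs from 0.072 to 0.094. Per1 went from 0.775 to 0.779 (adjusted p = 0.107). DESeq2 called 76, an unfiltered fit 16, a fit of the run's 6 samples 18 and limma-trend on FPKM 1.

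**Figure D4:**
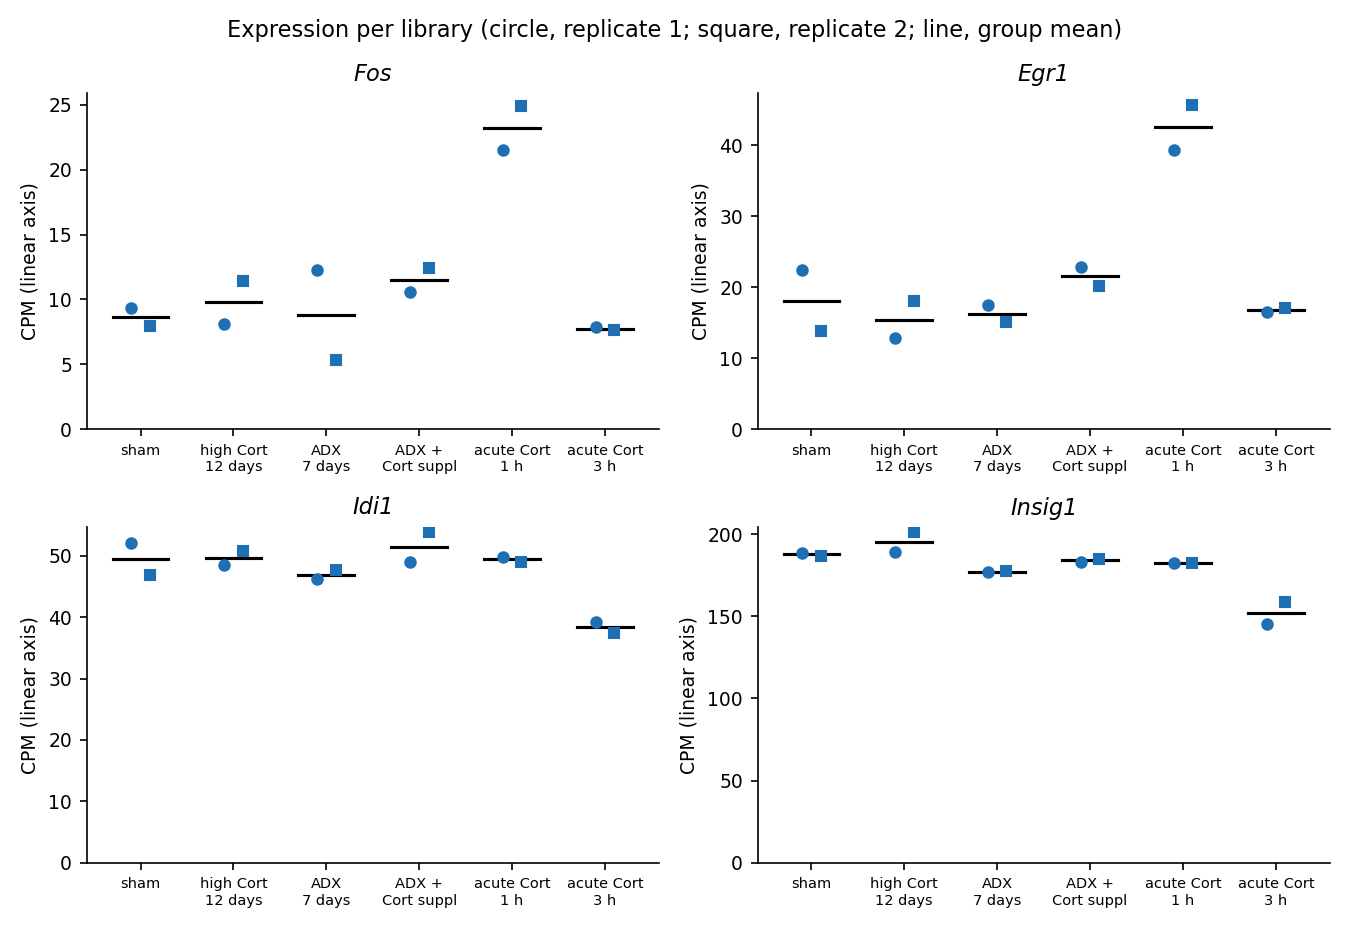
Levels of Fos, Egr1, Idi1 and Insig1 in CPM on the vertical axis for each library by group on the horizontal axis, with points for libraries and a bar for the group mean. Mean Egr1 was 42.51 CPM in 1 h acute and 16.77 CPM in 3 h acute.

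The comparison of 3 h acute with supplemented ADX asked the later question within the same run. Nab2, which encodes a co-repressor of Egr transcription factors, rose from 8.22 ± 0.366 to 13.65 ± 0.046 CPM (0.73 ± 0.09, adjusted p = 0.0177, n = 2 per group), the 1 gene called. Among 25 cholesterol synthesis genes, those lower adjusted over the list alone included Idi1 (-0.42 ± 0.07, adjusted p = 0.0674), Insig1 (-0.27 ± 0.05, adjusted p = 0.0674), Stard4 (-0.24 ± 0.05) and Hsd17b7. Camera gave the list an adjusted p of 0.007 (0.868 with an estimated correlation, 0.16 without 3 h acute replicate 1). Of 7 erythroid genes 3 were higher adjusted over the list alone (camera adjusted p = 0.00272; adjusted p = 0.682 with an estimated correlation; 0.0732 without 3 h acute replicate 2). So was 1 of 31 neuropeptide genes (camera adjusted p = 0.00769; adjusted p = 0.682 with an estimated correlation; 0.313 without 3 h acute replicate 2). Trh had 0.42 ± 0.13 (adjusted p = 0.270), Avp 0.35 ± 0.11 (adjusted p = 0.290), Crh 0.43 ± 0.19 (adjusted p = 0.409) and Sgk1 0.14 ± 0.13 (adjusted p = 0.696). The thalamus list ranked low with none called (camera adjusted p = 0.00481; adjusted p = 0.996 with an estimated correlation; turned with the thalamus score, which is made of this list, 0.968).

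At an unadjusted p under 0.05, 1612 genes differed, and simulated data with no effect gave 1.02 calls on average and at most 4. Nab2 lost the call in each fit without 1 library, with 719 to 1506 genes at an unadjusted p under 0.05 and none called by edgeR. With the thalamus score the log2 fold change of Nab2 went from 0.733 to 0.685, with an adjusted p of 0.0503. DESeq2 called 35 genes, a fit of the 4 samples 154, an unfiltered fit 20 and a fit of the run's 6 samples 2. Limma-trend on FPKM called none, with 1481 at an unadjusted p under 0.05.

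The comparison of 3 h acute with 1 h acute asked what changed between the times and is free of the choice of control. Per1 fell from 84.93 ± 3.47 to 50.85 ± 1.43 CPM (-0.74 ± 0.08, adjusted p = 0.00309, n = 2 per group). Hbb rose from 9.75 ± 0.699 to 18.51 ± 2.46 CPM (0.91 ± 0.14, adjusted p = 0.0413). Among 25 cholesterol synthesis genes, those lower adjusted over the list alone included Idi1 (-0.37 ± 0.07), Insig1 (-0.26 ± 0.05), Sqle and Stard4 (camera adjusted p = 1.70e-05; adjusted p = 0.391 with an estimated correlation).

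Of 35 immediate early genes, none passed over all genes, and 6 were lower adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.466 with an estimated correlation; 0.117 without 1 h acute replicate 1 and 0.237 without 3 h acute replicate 1). Egr1, Fos, Nr4a1, Nr4a3 and Junb passed over all genes by DESeq2 and in the fits of the 4 samples and of the run's 6 samples. Among them Fos stood at 7.76 ± 0.141 against 23.22 ± 2.37 CPM (-1.57 ± 0.36, adjusted p = 0.234). Egr1 stood at 16.77 ± 0.401 against 42.51 ± 4.42 CPM (-1.33 ± 0.23, adjusted p = 0.174), while Nr4a1 had -1.08 ± 0.16 (adjusted p = 0.0657) and Junb -0.78 ± 0.13 (adjusted p = 0.0657). Per1 was the 1 of 18 clock genes that fell over all genes, and 5 were lower adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.391 with an estimated correlation). Of 7 erythroid genes, Hbb rose over all genes and 4 adjusted over the list alone (camera adjusted p = 4.69e-06; adjusted p = 0.391 with an estimated correlation). The summed hemoglobin level was 32.35 and 26.73 CPM in the 1 h acute libraries and 53.35 and 65.04 CPM in the 3 h acute libraries. Mitochondrial genes were positive in 67 of 72, 13 of them called adjusted over the list alone (camera adjusted p = 3.36e-15; adjusted p = 0.391 with an estimated correlation). Ribosomal protein genes were positive in 79 of 87 (camera adjusted p = 3.15e-13; adjusted p = 0.426 with an estimated correlation). All 14 thalamus markers were positive (camera adjusted p = 0.000999; adjusted p = 0.581 with an estimated correlation); the list turned without 1 h acute replicate 2 (0.815) and with the thalamus score made of it (0.855). Avp (0.52 ± 0.12, adjusted p = 0.195) was 1 of 2 neuropeptide genes higher adjusted over the list alone (camera adjusted p = 0.00663; adjusted p = 0.423 with an estimated correlation).

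In this pair edgeR called 3 genes, 1 higher and 2 lower, with 1366 at an unadjusted p under 0.05, and simulated data with no effect gave 0.65 on average and at most 3. The count was 35 without 1 h acute replicate 1, 6 without 3 h acute replicate 1 and none without 3 h acute replicate 2, with 863 at an unadjusted p under 0.05 in the last. Per1 kept the call with the thalamus score and Hbb did not (adjusted p = 0.0702), though its log2 fold change went only from 0.915 to 0.866. Per1 had an adjusted p of 0.0534 and 0.0711 without 3 h acute replicates 1 and 2. Hbb had 0.298 without 1 h acute replicate 2 and 0.483 without 3 h acute replicate 2. DESeq2 called 24 genes, a fit of the run's 6 samples 10, a fit of the 4 samples 9 and an unfiltered fit 5.

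Whether sustained and acute corticosterone acted alike was tested as the difference of the high Cort effect against sham and the acute effect against supplemented ADX. The references were unlike, since supplemented ADX rats had lost the adrenal glands and already received corticosterone, and sham rats had not. The difference would therefore hold a difference between the references as well. Against the 1 h effect 20 genes differed, 13 higher and 7 lower in high Cort, and against the 3 h effect 21, 13 higher and 8 lower, with 11 genes in both. Gpd1 differed by 1.95 ± 0.22 (adjusted p = 0.024) and 1.79 ± 0.22 (adjusted p = 0.035). Abcg2 differed by 0.83 ± 0.10 (adjusted p = 0.0076) and 0.85 ± 0.10 (adjusted p = 0.0047), and Klf9 by 0.38 ± 0.06 (adjusted p = 0.021) and 0.43 ± 0.06 (adjusted p = 0.012). Fabp7 differed by -1.08 (adjusted p = 0.0077) and -1.13 (adjusted p = 0.0047), and Nes by -0.82 (adjusted p = 0.020) and -0.81 (adjusted p = 0.016). Per1 did not differ between high Cort and 1 h acute (0.12 ± 0.11, adjusted p = 0.73) but did between high Cort and 3 h acute (0.86 ± 0.11, adjusted p = 0.012). For Sgk1 the difference was not called against the 1 h effect (1.09 ± 0.18, adjusted p = 0.061) but was against the 3 h effect (1.21 ± 0.18, adjusted p = 0.045). For Crh neither difference was called, at -1.90 (adjusted p = 0.096) and -2.29 (adjusted p = 0.0503).

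The 15 glucocorticoid-induced genes called in high Cort, a set chosen on these samples, had a median log2 fold change of 0.609 there, 0.054 at 1 h and 0.046 at 3 h against supplemented ADX. The difference was called for 5 of them at each time. Among the 15, 1 gene, Per1, was called at 1 h and none at 3 h, and in supplemented ADX against ADX none was called. The count against the 1 h effect was 274 without 1 h acute replicate 1, 54 without high Cort replicate 2, 12 without sham replicate 1 and 10 without supplemented ADX replicate 1. It was 6 without 1 h acute replicate 2, 4 without high Cort replicate 1, 2 without supplemented ADX replicate 2 and 4 with the thalamus score. Against the 3 h effect it was 46 without high Cort replicate 2, 4 without high Cort replicate 1 and 4 without sham replicate 2. It was 7 and 2 without supplemented ADX replicates 1 and 2, and 12 and 9 without 3 h acute replicates 1 and 2.

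**Figure D5:**
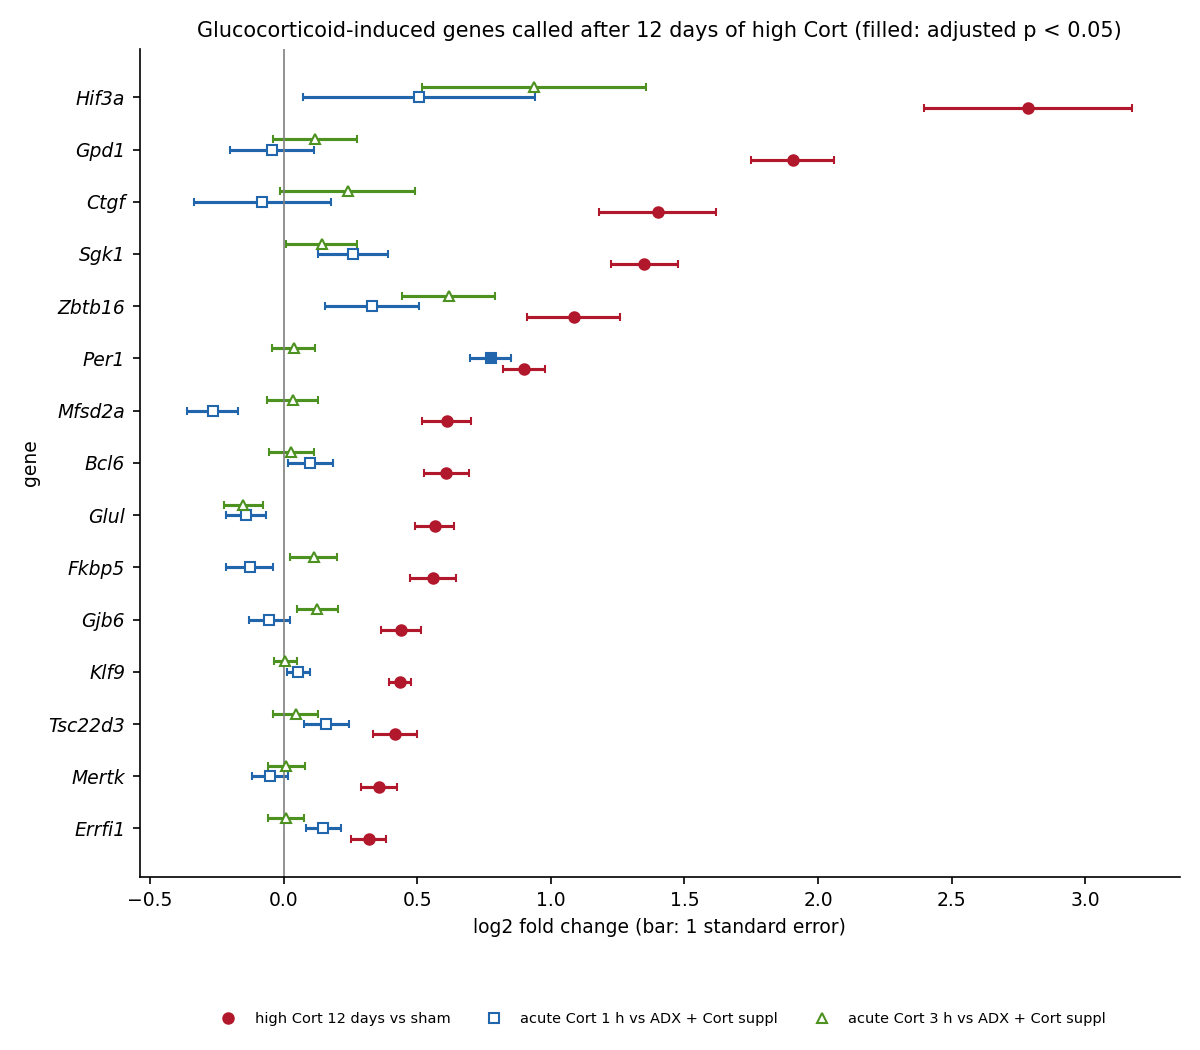
Log2 fold change with 1 SE (horizontal axis) of the 15 glucocorticoid-induced genes called in high Cort, listed on the vertical axis, for high Cort against sham and for 1 h and 3 h acute against supplemented ADX. Filled symbols mark an adjusted p under 0.05; the medians were 0.609, 0.054 and 0.046.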

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

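The tests of a batch shared by a run, of fewer endothelial cells, of ribosomal RNA and of a single library below were chosen after the results were seen, the last 2 in place of tests on genes that the same libraries had chosen, as was the thalamus score as a covariate.

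Between the acute times, Per1 differed by -0.74 and Hbb by 0.91 (log2, 3 h minus 1 h), each past the test of the difference between the times. The effect of high Cort against sham differed from that of 1 h acute against supplemented ADX in 20 genes and from that of 3 h acute in 21, by the test of the difference.

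Against sham edgeR called 1641 genes in 1 h acute and 1026 in 3 h acute, but 6 and 1 against supplemented ADX. As the source of most calls against sham, the tables argue against a batch shared by the libraries of one run, since supplemented ADX against ADX crosses the runs too and had 4 calls, and against depth, since 1567 and 816 genes were called with every library thinned to the shallowest, where the 6 and 1 calls against supplemented ADX became 12 and 6. In fits of the 4 samples alone the counts were 33 in supplemented ADX against ADX, 23 in 1 h acute against sham and 740 in 3 h acute against sham. For 1 h acute the argument against a batch therefore rests on the fit of all 12 libraries. More thalamic tissue in the sham dissections may account for part of the calls, but the thalamus score alone did not set their number. It was 6.79 in supplemented ADX and 6.14 in 1 h acute, with 6 calls between them. It was 7.16 in sham and 6.47 in 3 h acute, a gap of similar size, with 1026 calls. Of the 1641 genes, 76.3% differed in the same direction between the 2 sham libraries, the one with fewer thalamus markers minus the other, against 56.5% of genes not called, 53.6% of those called in high Cort and 53.3% in ADX. The thalamus markers Prkcd and Slc17a6 stood at 331.1 and 561.2 CPM in sham and at 80.77 and 353.3 CPM in 1 h acute, 1 of the 14 markers is also on another list, and an effect of acute corticosterone on the same genes stays open and untested.

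In high Cort 14 called genes counted as vascular, chosen after their values were seen, were lower, by log2 fold changes from -1.67 to -0.30, while Abcg2 and Mfsd2a of brain endothelium, chosen likewise, were called higher (0.91 and 0.61). Which cells of the tissue held the 14 transcripts was not tested, and Aplnr among them was called higher in ADX (0.76). Fewer endothelial cells in the dissections would lower all their abundant transcripts alike, but the median of 10 endothelial markers was -0.204, short of -0.426, which is 0.5 times the change of Kdr, by more than the SE of Kdr (0.075). Kdr was itself 1 of the 10, and its SE does not measure the spread of the markers, whose SD was 0.266. All but Abcb1a (0.14) were negative. A loss of cells therefore stays open, at least for the smaller changes, such as those of Pdgfrb, Slco1c1 and Itm2a. More ribosomal RNA in high Cort replicate 1 cannot be told apart: all 14 genes kept at least 0.5 times their change without that library and Kdr, Cd93, Mmp14 and Clec14a kept the call without each library, but they were chosen with it, and genes of the endothelial and mural list chosen on it and 1 sham library, by medians of 0.383 and 0.485, had 0.306 and 0.203 in the other libraries. Ribosomal RNA genes took 0.676% of the counts in high Cort replicate 1 and 0.2747% in replicate 2. A share so small argues against their fragments displacing those of other genes, but not against another difference of that library. An effect of sustained corticosterone on these genes stays open as well.

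Of 35 immediate early genes, 7 were higher 1 h after acute corticosterone than in supplemented ADX and Klf6 was lower, adjusted over the list alone, with a median log2 fold change of 0.793 over these 8. A single library cannot be told apart: the median was 0.782 without 1 h acute replicate 1 and 0.716 without replicate 2, but the genes were chosen on these libraries; those chosen on 1 library of each group had medians of 0.272 to 0.627 in the other libraries, by choices at 0.773 to 0.949, with no gene chosen in 1 of 4 splits, and camera gave the whole list an adjusted p of 0.0727 without replicate 1 and 0.000471 without replicate 2, where it ranged from 5.63e-05 to 0.564 over all alternatives. With the thalamus score in the model the median was 0.532, above 0.397, which is 0.5 times 0.793, by a median margin of 0.119 that lies within its SD of 0.293, so tissue composition cannot be told apart from the treatment here. Injection and handling cannot be told apart from corticosterone either, since 0 of the groups were vehicle controls, and at 3 h the same genes had a median of -0.075.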

How the results depend on the processing

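The fits with the thalamus score, the fits of a run's 6 samples and the leave-one-out fits of the differences were chosen after the results were seen. Limma-trend on FPKM was not run for comparisons that cross the processing runs. With RLE size factors 177 of 179 named gene values kept their direction and side of the threshold, and with the stricter filter 178; the median log2 fold change of all genes was at most 0.0101 from 0 under TMM and RLE. Over all alternatives 1681 of 2239 named gene values stayed so, 497 lost the call, 59 gained one and 2 turned. DESeq2 entered with 149 values only. A named gene without an adjusted p from DESeq2 was left out of that alternative, and of the ranges over all alternatives, rather than counted as lost. Leaving out 1 library ended the call in 255 of 716 values. Of 800 list values 635 stayed so, 149 lost the call, 8 gained one and 8 turned. These totals include genes and lists that were not called in the main fit and had no call to lose, so the share of calls lost was larger. The cause was not tested for the changes below, except that fits of fewer samples have fewer degrees of freedom and that the thalamus score is made of the thalamus list. A library left alone in its group was assumed to vary like the other groups.

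The counts in the order high Cort, ADX, supplemented ADX against ADX, supplemented ADX against sham, 1 h and 3 h acute against sham, 1 h and 3 h acute against supplemented ADX, and 3 h against 1 h acute were 112, 30, 4, 2, 1641, 1026, 6, 1 and 3. The thalamus score gave 175, 14, 7, 5, 2, 7, 0 and 0 in the first 8 comparisons, the last pair with 629 and 1127 at an unadjusted p under 0.05. DESeq2 gave 123, 14 and 42 in ADX and the supplemented comparisons, 76 and 35 in the acute groups against supplemented ADX and 24 for 3 h against 1 h. A fit of the 4 samples gave 46 in high Cort, 33 and 23 in the supplemented comparisons, 23 in 1 h acute against sham, 154 in 3 h acute against supplemented ADX and 9 for 3 h against 1 h. Without a filter the count was 48 in ADX, 11 in supplemented ADX against sham, 16 and 20 in the acute groups against supplemented ADX and 5 for 3 h against 1 h. A fit of the run's 6 samples gave 99 in ADX, 18 and 2 in the acute groups against supplemented ADX and 10 for 3 h against 1 h. Limma-trend on FPKM with pseudocounts of 1 and 0.1 gave 69 and 67 in high Cort, 8 and 8 in ADX, and 1 and 1 in 1 h acute against supplemented ADX. In 3 h acute against supplemented ADX it called 0 and 0, with 1481 and 1482 genes at an unadjusted p under 0.05. A replicate block, although the replicate numbers have no stated meaning, gave 19 in ADX, 1 in supplemented ADX against sham and 3 in 1 h acute against supplemented ADX. Leaving out each library in turn gave 23 to 121 in high Cort, 4 to 148 in ADX, 0 to 4 and 0 to 64 in the supplemented comparisons, and 144 to 2125 and 81 to 997 in 1 h and 3 h acute against sham. It gave 1 to 624 and 0 to 0 (719 to 1506 at an unadjusted p under 0.05) in 1 h and 3 h acute against supplemented ADX, and 0 to 35 for 3 h against 1 h. For the differences the thalamus score gave 4 genes against the 1 h effect and 282 for high Cort against ADX, and leaving out a library gave 2 to 274, 2 to 46 and 157 to 386. Of 252 list tests camera called 77, fry 14 and camera with an estimated correlation 0, with a lowest adjusted p of 0.057.

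Under the thalamus score Nr3c1 and Srebf2 in 1 h acute against sham turned to 0.029 and -0.0105. The neuron list turned in 1 h acute against supplemented ADX (adjusted p = 0.929), and the thalamus list in 3 h acute against supplemented ADX (0.968) and against 1 h acute (0.855). For the latter an adjusted p of 3.24e-11 without 1 h acute replicate 1 stood against 0.815, turned, without 1 h acute replicate 2. The cell cycle list in high Cort turned on FPKM (0.981 and 0.96), and the astrocyte list, which was not called, turned without sham replicate 2 (0.815) and without high Cort replicate 1 (0.756), against 0.421 without sham replicate 1. Depth was 17674159 to 36249006 fragments, and 42% of genes simulated to change 1.3-fold were found in 1 h acute against supplemented ADX.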

Other observations

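The gene groups described first here were tested on lists fixed before the data were examined; the thalamus score as a covariate was the only test in this part chosen after the result was seen.

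In high Cort against sham, several further marker lists ranked low. Of 7 erythroid genes, 3 were lower adjusted over the list alone (camera adjusted p = 1.75e-06; adjusted p = 0.14 with an estimated correlation). Of 13 meningeal and fibroblast markers 3 were, the collagen gene Col1a1, Igf2 and Ogn (camera adjusted p = 7.84e-05; adjusted p = 0.236 with an estimated correlation). Of 17 oligodendrocyte markers none passed (camera adjusted p = 0.000263; adjusted p = 0.647 with an estimated correlation; 0.352 without sham replicate 1 and 0.09 without high Cort replicate 1). The lists of 15 microglia markers (camera adjusted p = 0.000756; adjusted p = 0.205 with an estimated correlation) and 26 interferon response genes (camera adjusted p = 0.00377; adjusted p = 0.757 with an estimated correlation) ranked low too. Of 12 oligodendrocyte precursor markers Enpp6 fell over all genes (camera adjusted p = 0.00245; adjusted p = 0.324 with an estimated correlation). Of 20 suprachiasmatic and anterior hypothalamic markers Avp, Otp, Pou3f2 and Sim1 were lower adjusted over the list alone (camera adjusted p = 0.024; adjusted p = 0.14 with an estimated correlation); Otp and Sim1 encode transcription factors of the developing PVH. The 18 cell cycle genes had no call over all genes (camera adjusted p = 0.0084; adjusted p = 0.14 with an estimated correlation; 0.121 without sham replicate 1 and 0.0971 without high Cort replicate 1), and the direction of this list turned by limma-trend on FPKM with either pseudocount (0.981 and 0.96).

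The changes of 1 h acute and of ADX, both against sham, correlated at 0.848 across 10180 genes, where the shared sham libraries gave 0.503 in 40 simulations. The simulated genes varied independently, while the real sham libraries differed in thalamus score (6.97 and 7.35), so 0.503 may be too low a baseline. The thalamus score was 6.14 in 1 h acute, 6.73 in ADX and 7.16 in sham, and with it as a covariate the calls went from 1641 to 2 and from 30 to 14. The median log2 fold change of the 1641 genes toward their call went from 0.302 to 0.101. In ADX a lost call was not always a lost change: over all alternatives Heph lay between -1.12 and -0.90, while Cyp4f4 varied more (-0.96 to -0.57). What made the changes alike was not tested. Called genes higher in both numbered 14 and lower in both 6. The changes of 1 h and 3 h acute against supplemented ADX correlated at 0.598, against 0.479 in the simulations. Genes are not independent replicates, and the control libraries were not split between the comparisons.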
